A study of Caenorhabditis elegans with 8 samples.

How the data were processed

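Whole young adult worms were profiled by sequencing of total RNA with the ScriptSeq v2 kit, per the labels, in 8 libraries. Synchronized larvae were fed double-stranded RNA directed against rege-1 or a mock control. The 4 groups were N2 mock, N2 rege-1 RNAi, glp-1 mock and glp-1 rege-1 RNAi, with 2 libraries each, taken from the sample titles. The authors deposited raw counts per gene and library for mRNA and, in a separate table, for introns. The authors also deposited log2 values of both tables, each of which equals the log2 of the count scaled to the mean library total plus a pseudocount, as checked from the values. The aligner, genome build, annotation and counting tool are not given in the sources used here, nor whether counting used the strand of the reads, so that genes overlapping others could share counts.

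Each table held 20182 genes with WormBase identifiers, of which 18778 had a symbol and 19513 were found in the Ensembl release 115 annotation (WBcel235), the source of the positions. The width column of the mRNA table was a multiple of 3 for 96.6% of genes, and it is taken as coding length. Library totals ranged from 26127079 to 30093967 mRNA counts and from 464385 to 684124 intron counts. In each library 4 genes took from 17.0 to 38.1% of the intron counts.

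Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 15321 genes for mRNA, 5042 for introns and 4999 in both. Libraries were scaled by TMM, and the 4 groups were fitted together by the quasi-likelihood method with robust estimation (4 residual degrees of freedom). The quasi-likelihood F test is two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The contrasts were RNAi against mock in each strain, their difference (N2 minus glp-1), and glp-1 against N2 under mock. The change of mRNA beyond that of introns was tested in 1 model of both kinds of count with the library as a block.

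Named genes were rege-1 and ets-4, then the 10 genes in each direction with the largest log2 change among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups (5 in each direction for the difference and for strain). From each described list, up to 4 members with the lowest p were named. Gene lists were tested by camera in limma 3.58.1 with its preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusting over the lists in each contrast. Of 35 lists, 34 had at least 5 tested members. They covered ETS factors, mRNA decay, yolk, lipid metabolism, DAF-16 targets, immunity, stress and detoxification, autophagy, cuticle and molting, germline and early embryo, and markers of tissues. With an estimated correlation 0 lists were called in any of the 4 contrasts. Groups, contrasts, lists, naming rule and the alternatives except 1 were fixed before the data were examined.

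Alternatives were other size factors, library size alone, no filter, a replicate block, a fit of the compared groups alone, DESeq2 1.42.0, limma on the deposited log2 values, fry for lists, and each library left out in turn. A fit with each library's trend over coding length removed was added after a trend had been seen. On simulated data for N2, edgeR, DESeq2 and limma were tested on genes with known changes. Counts were drawn for each gene on its own, without deviations that many genes of a library share. False calls in these libraries may therefore be more frequent than the simulated rates. Of genes changed 2-fold and 4-fold, edgeR found 70% and 92% with 4.1% false calls, DESeq2 68% and 87% with 9.4%, and limma 68% and 92% with 4.2%. For introns edgeR found 14% and 68% with 8.9% false calls, above the threshold of 5%, and for mRNA beyond introns 9% and 59% with 1.4%. The labels do not say that replicate numbers pair the samples, so the main model has no replicate block. The replicates of each group differed by more than counting error, with a mean chi-square per gene of 43.0 in N2 mock, 32.4 in N2 RNAi, 3.61 in glp-1 mock and 61.4 in glp-1 RNAi where counting error gives 1. No outlier test was made, since groups held 2 libraries.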

Results

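The series profiled total RNA of whole Caenorhabditis elegans at the young adult stage, with the aim, by its title, of finding targets of the RNase domain protein that the gene rege-1 encodes. Worms of the laboratory wild type N2 and of a glp-1 mutant background were fed double-stranded RNA against rege-1, which is meant to lower a gene's mRNA by RNA interference (RNAi), or a mock control. GLP-1 is a Notch receptor that keeps germline stem cells dividing. The labels state 25 °C for the glp-1 animals, taken here as the restrictive temperature, and no temperature for N2. The 4 groups (N2 mock, N2 RNAi, glp-1 mock, glp-1 RNAi) held 2 libraries each. The deposited counts of every library were split into coding counts, called mRNA here, and intron counts. Library totals were 29550649 and 26127079 mRNA counts for N2 mock, 28169509 and 29688933 for N2 RNAi, 30093967 and 29001469 for glp-1 mock, and 27541201 and 28165959 for glp-1 RNAi. Intron totals were far smaller, from 464385 to 684124 per library. Changes are on the log2 scale with their standard error (SE), levels are CPM, which is counts scaled to a fixed library total, as mean ± SD of n = 2 libraries, and adjusted p is from edgeR over all genes tested. The largest changes are those among genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups compared. The labels do not state separate cultures, so each p measures the spread between these libraries, which could be technical.

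The targeted gene, rege-1 (WBGene00016260, protein coding, chromosome I from 6954414 to 6961139, minus strand, WBcel235), went up and not down in the libraries labelled rege-1 RNAi. In N2 its mRNA counts were 396 and 354 under mock and 2664 and 2137 under RNAi, and in glp-1 they were 495 and 480 under mock and 1950 and 1891 under RNAi. Its intron counts were 15 and 15 under mock and 4166 and 3265 under RNAi in N2, and 40 and 25 against 240 and 296 in glp-1. Knockdown can therefore not be read from these counts, and every direction given for RNAi rests on the labels of the libraries. The change of rege-1 mRNA was 2.70 (SE 0.15, adjusted p = 7.19e-07) in N2 and 2.11 (SE 0.15, adjusted p = 6.53e-06) in glp-1, and that of its introns was 7.91 (SE 0.44, adjusted p = 1.25e-10) and 3.18 (SE 0.36, adjusted p = 2.69e-05).

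**Figure D1:**
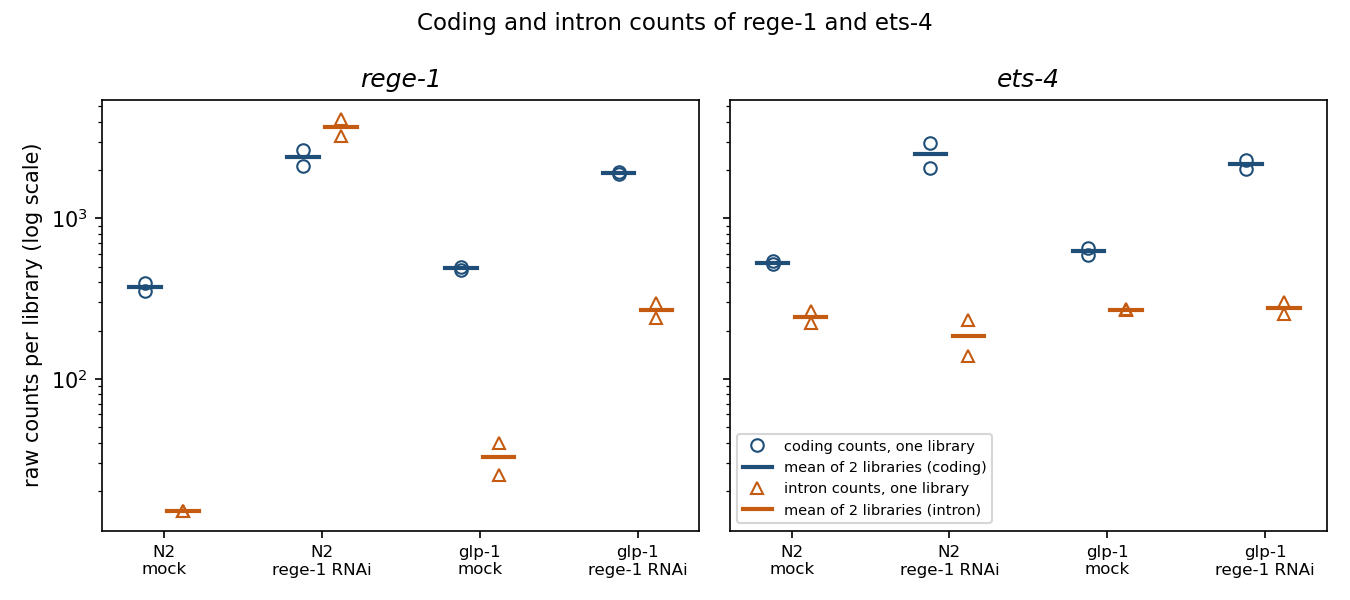
Raw coding counts (circles) and intron counts (triangles) per library on a log axis for rege-1 and ets-4 in the 4 groups, with bars at the mean of 2 libraries. Both kinds of count are higher for rege-1 in the libraries labelled RNAi, whereas for ets-4 the coding counts reach 2027 to 2958 there and the intron counts lie between 138 and 300 in all 8 libraries.

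The comparison of rege-1 RNAi with mock in N2 asks which mRNAs change with the treatment in wild type worms. The mRNA of ets-4 (WBGene00017687, protein coding, chromosome X from 6518883 to 6522667, plus strand, WBcel235), which encodes an ETS family transcription factor, rose from 19.7 ± 2.18 to 93.5 ± 21.3 CPM (log2 2.25, SE 0.17, adjusted p = 8.56e-06). The saposin-like gene spp-12 (WBGene00004997) rose from 0.162 ± 0.118 to 206 ± 15.7 CPM, and the C-type lectin gene clec-70 (WBGene00021581) from 0.418 ± 0.152 to 217.5 ± 26.3 CPM. The UDP-glucuronosyltransferase gene ugt-18 (WBGene00013900) went from 1.67 ± 0.268 to 488 ± 28.4 CPM. The enoyl-CoA hydratase family gene ech-9 (WBGene00001158) went from 4.63 ± 0.107 to 1306 ± 28.8 CPM, the aspartyl protease gene asp-12 (WBGene00017678) from 10.6 ± 0.286 to 2852 ± 945 CPM, and the acyl-CoA oxidase gene acox-1.5 (WBGene00008167) from 30.6 ± 7.18 to 1137 ± 147 CPM. The remaining genes of the 10 largest rises were clec-72 (log2 6.14), Y65B4BR.1 (log2 5.19), spp-9 and WBGene00044642. The last pair had 1 count each in both mock libraries together, and ratios of 380 (95% counting interval 67.7 to 15030) for spp-9 and 441 (78.8 to 17470) for WBGene00044642. Such intervals cover counting error only.

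The C-type lectin gene clec-218 (WBGene00020938) fell in N2 from 40.0 ± 1.15 to 1.29 ± 0.267 CPM (log2 -4.95, SE 0.23, adjusted p = 1.71e-07), and WBGene00019208 from 18.99 ± 0.748 to 0.940 ± 0.655 CPM. The acid sphingomyelinase gene asm-3 (WBGene00000213) fell from 83.5 ± 17.1 to 9.78 ± 2.42 CPM and the ferritin gene ftn-1 (WBGene00001500) from 5.03 ± 0.0725 to 0.617 ± 0.0935 CPM. The other 6 of the 10 largest falls were cutl-18, C30G12.2, C52D10.3, WBGene00016875, pho-8 and the cytochrome P450 gene cyp-34A7, with log2 changes from -3.60 to -2.72. In all, 480 genes were higher and 254 lower among 15321 tested by edgeR. The total of 734 was 423 without N2 mock replicate 1 and 437 without N2 RNAi replicate 2.

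Lysozyme, C-type lectin, infection response and intestine marker genes rose more often than they fell in N2, while antimicrobial peptide genes were called lower as a list. Of 33 measured lysozyme and saposin-like genes, 12 rose and 1 fell (18 and 2 adjusted over the list alone), among them spp-2 (log2 2.93) and lys-4 (log2 2.36). Of 153 C-type lectin genes, 39 rose and 6 fell (45 and 9 adjusted over the list alone), and of 18 infection response genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), with clec-60 at log2 4.83 and clec-67 at log2 3.39. Of 18 intestine markers, 8 rose and 0 fell (11 and 1 adjusted over the list alone), among them the aspartyl protease genes asp-3 (log2 3.06) and asp-1 (log2 2.35) and the proton pump subunit gene vha-6 (log2 1.34). Camera with its preset correlation called these 4 lists higher (adjusted p = 5.56e-25, 6.57e-16, 4.46e-19 and 3.63e-16). With an estimated correlation the adjusted p was 0.111 for the first 3 lists and 0.0875 for the intestine markers.

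Lipid genes changed in N2 in both directions. Of 45 beta-oxidation genes, 11 rose and 6 fell (12 and 7 adjusted over the list alone), with hacd-1 at log2 2.12 and cpt-3 at log2 2.34 next to ech-9 and acox-1.5. Of 16 lipases and lipid droplet proteins, 3 rose, the lysosomal lipase gene lipl-1 (log2 4.13), fil-1 (4.17) and lipl-2 (1.11), and 1 fell (4 and 2 adjusted over the list alone). Of 26 fatty acid synthesis genes, 3 rose, among them the desaturase gene fat-5 (log2 2.73), and 1 fell, dgat-2 (-1.13), with 7 and 2 adjusted over the list alone. These lists were called higher (adjusted p = 2.76e-06, 0.000105 and 0.00857), with adjusted p = 0.111, 0.111 and 0.501 with an estimated correlation. The call on fatty acid synthesis ended without N2 mock replicate 2 (adjusted p = 0.0621) and without N2 RNAi replicate 1 (adjusted p = 0.11).

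Of the 6 vitellogenin genes, which encode yolk proteins, vit-3 (log2 -1.50), vit-4 (-1.32), vit-1 (-1.23) and vit-5 (-0.83) fell in N2, while vit-2 was at 0.26 (adjusted p = 0.834) and vit-6 at 0.30 (adjusted p = 0.705). The list was called lower (0 and 4 adjusted over the list alone, adjusted p = 7.9e-05), with adjusted p = 0.453 with an estimated correlation. The call on vit-1 ended without N2 mock replicate 2 (adjusted p = 0.118) and N2 RNAi replicate 1 (0.108), and that on vit-5 without N2 mock replicate 2 (0.105), N2 RNAi replicate 1 (0.0981) and N2 RNAi replicate 2 (0.0964). Several vitellogenin genes are near-identical copies, so that reads could be shared among them.

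Genes of detoxification and genes that the FOXO transcription factor DAF-16 induces fell more often than they rose in N2. Of 62 cytochrome P450 genes, 12 fell and 5 rose (19 and 5 adjusted over the list alone), including cyp-35A2 (log2 -2.41) and cyp-34A9 (-2.02). Of 64 UDP-glucuronosyltransferase genes, 15 fell and 6 rose (29 and 8 adjusted over the list alone), and of 45 glutathione S-transferase genes 4 fell and 0 rose (7 and 1 adjusted over the list alone), with gst-4 at -1.05. Of 21 DAF-16 induced genes 7 fell and 2 rose (8 and 3 adjusted over the list alone), with pud-4 at -2.52 and ttr-44 at -2.20, and of 40 antimicrobial peptide genes 3 fell and 0 rose (7 and 0 adjusted over the list alone). Camera called these 5 lists lower (adjusted p = 2.04e-05, 3.93e-05, 0.0201, 0.000158 and 0.000517), and the adjusted p was 0.111, 0.602, 0.631, 0.111 and 0.602 with an estimated correlation. The glutathione S-transferase call ended without N2 mock replicate 2 (adjusted p = 0.0511) and N2 RNAi replicate 2 (0.286), and with the trend of each library over coding length removed (0.0658).

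Oogenesis and eggshell genes were called higher as a list in N2 (median log2 0.20, adjusted p = 0.0161, or adjusted p = 0.602 with an estimated correlation), and 0 of its 32 genes passed singly or adjusted over the list alone. The ETS list was called higher on ets-4, the 1 gene of 7 to pass (adjusted p = 0.0476, or adjusted p = 0.501 with an estimated correlation). The oogenesis call ended without N2 mock replicate 2 (adjusted p = 0.202) and N2 RNAi replicate 2 (0.0923), and the ETS call without N2 mock replicate 1 (0.451) and N2 RNAi replicate 2 (0.163), and with the trend over coding length removed (0.0634). Camera made no call in N2 for the lists of body wall muscle, pharynx, neuron and hypodermis markers, mitotic and meiotic germline genes, major sperm proteins, other spermatogenesis genes, early zygotic genes, molting cycle genes, histones, ribosomal proteins, heat shock proteins, autophagy and lysosome genes or germline-less longevity factors, in each of which 0 members passed over all genes, while 3 of 14 heat shock genes and 1 of 12 pharynx markers were higher adjusted over the list alone and 0 in the rest. The other lists without a call were cuticle collagens (3 of 130 fell, 2 adjusted over the list alone), neuropeptides and insulins (1 of 114 rose and 1 fell), pals genes (2 of 21 rose), DAF-16 repressed genes (1 of 10 rose and 2 fell, 2 and 2 adjusted over the list alone) and mRNA decay factors, of which rege-1 alone passed among 30. The DAF-16 repressed list had a median of 0.13 and a mean of 0.03, while camera ranked it lower (adjusted p = 0.371). The tables held 0 genes of the mitochondrially encoded list.

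The comparison of rege-1 RNAi with mock in glp-1 repeats the question in the mutant background. The mRNA of ets-4 rose from 19.8 ± 0.648 to 75.4 ± 6.96 CPM (log2 1.93, SE 0.17, adjusted p = 3.85e-05). The gene clec-70 rose from 0.0635 ± 0.00209 to 81.0 ± 2.36 CPM, ugt-18 from 0.567 ± 0.250 to 262 ± 33.6 CPM, ech-9 from 3.08 ± 0.683 to 717 ± 181 CPM, asp-12 from 5.63 ± 0.903 to 499 ± 4.16 CPM, and lipl-1 (WBGene00010062) from 5.08 ± 0.212 to 203 ± 31.2 CPM. For spp-12 the mock libraries held 2 counts together against 2416 under RNAi, a ratio of 1320 (95% counting interval 365 to 10910). The other 4 of the 10 largest rises were clec-52, clec-60, clec-169 and F42A10.7, with log2 changes from 5.48 to 4.22.

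The gene sysm-1 (WBGene00011979, log2 -3.87, SE 0.45, adjusted p = 0.000392) fell most in glp-1, followed by clec-218 (log2 -3.26, SE 0.23, adjusted p = 7.76e-06) and C30G12.2 (WBGene00016274, log2 -2.54, SE 0.27, adjusted p = 0.000212). The cytochrome P450 genes cyp-35A2 and cyp-25A1 fell by 2.44 and 2.06 on the log2 scale. The other 5 of the 10 largest falls were WBGene00019208, WBGene00016875, the dehydrogenase gene dhs-26, R05H10.7 and W02H3.1, with WBGene00019208 lowest at log2 -2.12. Of these dhs-26 did not pass without glp-1 mock replicate 2 (adjusted p = 0.0523) or glp-1 RNAi replicate 1 (0.11). In all, 289 genes were higher and 125 lower by edgeR. The total of 414 was 188 and 196 without glp-1 mock replicate 1 or 2. It was 1491 without glp-1 RNAi replicate 2, of which 1104 were lower, with a median coding length of 2060 bases against 1095 for all tested genes.

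Lysozyme, C-type lectin and intestine marker genes also rose more often than they fell in glp-1, and the antimicrobial peptide list was not called (0 of 40 rose and 1 fell, 0 and 2 adjusted over the list alone, median log2 0.06, adjusted p = 0.991). Of 33 lysozyme and saposin-like genes 15 rose and 1 fell (17 and 1 adjusted over the list alone), of 153 C-type lectin genes 26 rose and 4 fell (33 and 6 adjusted over the list alone), and of 18 infection response genes 4 rose and 2 fell (6 and 2 adjusted over the list alone, median log2 0.15). Of 18 intestine markers 7 rose and 0 fell (8 and 0 adjusted over the list alone), among them asp-1 (log2 2.54), asp-3 (2.46) and the cysteine protease gene cpr-1 (1.74). Of 45 beta-oxidation genes 7 rose and 1 fell (12 and 4 adjusted over the list alone), and of 16 lipases and lipid droplet proteins 3 rose, among them lipl-1 and fil-1 (3.79), and 1 fell (4 and 3 adjusted over the list alone). The preset correlation called these 6 lists higher (adjusted p = 1.19e-34, 6.4e-13, 0.000157, 4.64e-16, 9.09e-08 and 0.00046), with adjusted p = 0.105, 0.187, 0.552, 0.0726, 0.105 and 0.121 with an estimated correlation. The median of the lipase list was -0.03 and its mean 0.38.

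Vitellogenin genes fell in glp-1 too, with vit-3 at log2 -1.59, vit-5 at -1.31, vit-4 at -1.28 and vit-1 at -1.18, while vit-2 was at -0.07 (adjusted p = 0.963) and vit-6 at -0.22 (adjusted p = 0.793). The list was called lower (0 and 4 adjusted over the list alone, adjusted p = 3.38e-09), with adjusted p = 0.187 with an estimated correlation. The call on vit-1 ended whichever of the 4 glp-1 libraries was left out (adjusted p = 0.133 and 0.146 without mock replicate 1 and 2, and 0.258 and 0.0957 without RNAi replicate 1 and 2).

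Of the cytochrome P450 genes 6 fell and 3 rose in glp-1 (11 and 4 adjusted over the list alone), and of the UDP-glucuronosyltransferase genes 13 fell and 2 rose (15 and 4 adjusted over the list alone). Of the DAF-16 induced genes 7 fell and 2 rose (7 and 4 adjusted over the list alone), and of 10 DAF-16 repressed genes 2 fell, the DNase gene nuc-1 (log2 -1.07) and dod-17 (-1.12), and 1 rose (3 and 1 adjusted over the list alone). These 4 lists were called lower (adjusted p = 0.000119, 0.00274, 0.00506 and 0.0207), with adjusted p = 0.187, 0.784, 0.187 and 0.423 with an estimated correlation. The ETS list (ets-4 alone passing, adjusted p = 0.0364) and the neuropeptide and insulin list (2 of 114 rose and 1 fell, adjusted p = 0.00856) were called higher, with adjusted p = 0.51 and 0.893 with an estimated correlation. Without glp-1 RNAi replicate 1 the neuropeptide list turned lower (adjusted p = 0.851) and the UDP-glucuronosyltransferase call ended (0.523). The neuropeptide call also ended with the trend over coding length removed (0.0985). The ETS call ended without glp-1 mock replicate 1 (0.195), RNAi replicate 1 (0.0576) or RNAi replicate 2 (0.27), the DAF-16 induced call without RNAi replicate 2 (0.403), and the DAF-16 repressed call without mock replicate 1 (0.109), mock replicate 2 (0.0612) or RNAi replicate 2 (0.27). The other 21 lists tested were not called.

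The calls of the 2 strains overlapped beyond chance. Of the genes called higher, 261 were shared, which is 90.3% of those in glp-1 and 54.4% of those in N2, against 9.05 for independent lists (odds ratio 630, Fisher's exact test, log10 of the upper-tail p -391.5). Of those called lower, 94 were shared against 2.07 for independent lists (odds ratio 283, two-sided Fisher's exact test, p = 2.16e-147). The strains used separate mock libraries, and 0 genes were called in opposite directions. Both contrasts share the dispersion estimate of each gene, so the numbers for independent lists may be too low. Over the 793 genes called in either strain, log2 changes correlated across genes with Pearson's r = 0.89 and Spearman's rho = 0.89, and over all 15321 genes with 0.61 and 0.26, although genes are not independent replicates. The change was smaller in glp-1 for 81.3% of these 793 genes, with a median ratio of glp-1 to N2 of 0.68. More of them were called in N2, and that choice favors larger changes there.

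**Figure D2:**
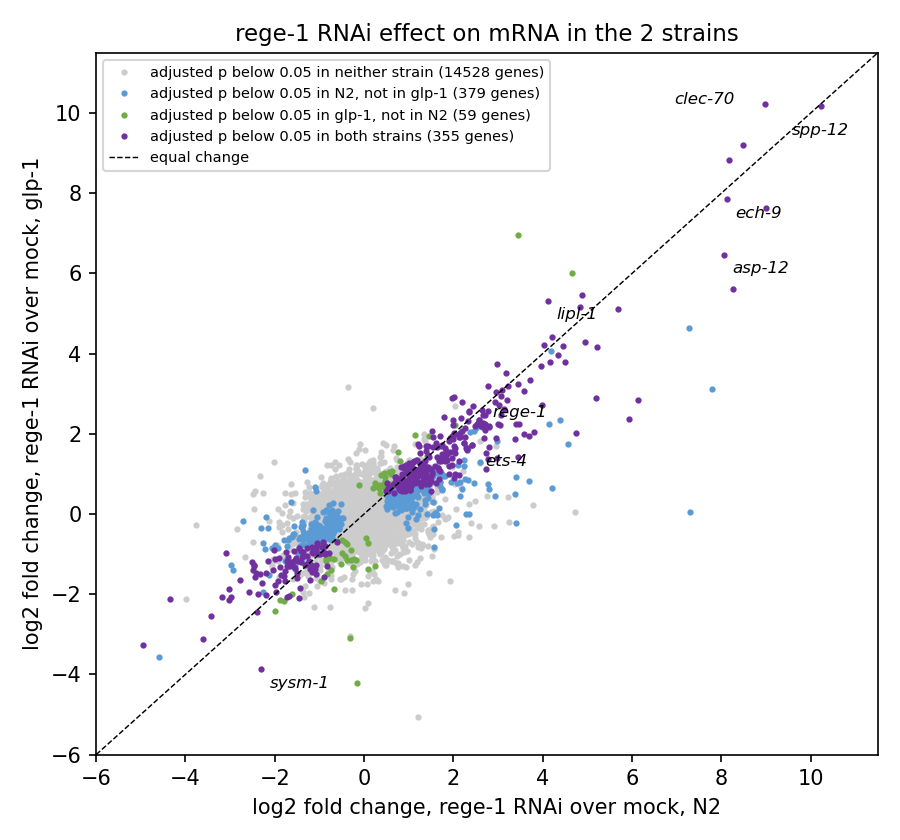
Log2 change of mRNA under the rege-1 RNAi label over mock in N2 (x axis) and in glp-1 (y axis), each point a gene, colored by the strains in which its adjusted p lies below 0.05. In both strains 355 genes were called, among them ets-4 at 2.25 in N2 and 1.93 in glp-1.

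The test of the difference between strains asks whether the RNAi response depends on the background. It called 4 genes with the larger rise in N2 and 0 with the larger rise in glp-1. By edgeR 828 of the 15321 genes tested had an unadjusted p below 0.05, little more than the share that chance gives. DESeq2 called 30, 19 with the larger value in N2 and 11 with the larger value in glp-1, and limma called 4, all with the larger value in N2. The cytochrome P450 gene cyp-13A12 (WBGene00008810) went from 0.306 ± 0.212 to 5.82 ± 0.287 CPM in N2 and from 1.08 ± 0.0804 to 1.70 ± 0.155 CPM in glp-1. The C-type lectin gene clec-72 (WBGene00021583) went from 0.471 ± 0.226 to 34.04 ± 6.41 CPM in N2 and from 2.25 ± 0.119 to 16.3 ± 0.712 CPM in glp-1, and clec-125 (WBGene00021118) from 1.75 ± 0.00130 to 13.4 ± 0.216 CPM and from 16.9 ± 1.41 to 22.9 ± 2.09 CPM. The carnitine palmitoyltransferase gene cpt-3 (WBGene00021703) went from 1.73 ± 0.133 to 8.78 ± 0.996 CPM in N2 and was at 6.36 ± 0.927 and 6.36 ± 0.299 CPM in glp-1. The difference was 0.59 for rege-1 mRNA (SE 0.20, adjusted p = 0.838) and 0.32 for ets-4 mRNA (SE 0.23, adjusted p = 0.875). The count of 4 fell to 0 without N2 mock replicate 1, N2 mock replicate 2 or glp-1 mock replicate 2, to 1 without glp-1 mock replicate 1 and to 2 without glp-1 RNAi replicate 1, and was 405 without glp-1 RNAi replicate 2.

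As lists, infection response genes differed by a median of 0.80 (N2 minus glp-1), autophagy and lysosome genes by 0.20, antimicrobial peptide genes by -0.57 and neuropeptide and insulin genes by -0.22. In each of these lists 0 genes passed singly, and adjusted over the list alone 11 of the 18 infection response genes had the larger value in N2 and 0 the larger in glp-1, while 0 passed in the other lists. Camera called these 4 lists (adjusted p = 3.12e-13, 0.00886, 1.27e-05 and 0.00604), each with adjusted p = 0.913 with an estimated correlation. Without glp-1 RNAi replicate 1 the call on antimicrobial peptides ended (adjusted p = 0.156) and neuropeptides and insulins turned (0.951), and the call on autophagy and lysosome genes ended without N2 mock replicate 1 (0.139) or N2 RNAi replicate 2 (0.243). With the trend of each library over coding length removed, the neuropeptide and insulin call ended (median -0.08, adjusted p = 0.448) and the other 3 lists stayed called. The other 30 lists tested were not called.

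Intron counts, which stand for unspliced RNA, moved with the mRNA for most of the called genes whose introns could be tested, which were 308 of 734 in N2 and 173 of 414 in glp-1. In N2, 43 genes were higher and 11 lower in introns among 5042 tested, and 50 of these 54 were also called in mRNA in the same direction. In glp-1, 32 were higher and 3 lower, of which 30 were called in mRNA in the same direction. Of the genes called in mRNA that had testable introns, 266 of 308 in N2 (86.4%) and 165 of 173 in glp-1 (95.4%) had an intron change of the same sign. Introns counted in the RNAi libraries alone can pass the filter, which favors the same sign for strongly raised genes. The share among genes not called in mRNA is not given here for comparison. The correlations that follow are of the genes called in mRNA with testable introns. Among them the log2 changes of mRNA and introns correlated across genes with Pearson's r = 0.81 and Spearman's rho = 0.79 in N2 and 0.84 and 0.82 in glp-1. The intron total of 54 in N2 was 28 without N2 mock replicate 1 and 32 without N2 RNAi replicate 1, and that of 35 in glp-1 was 12 and 8 without mock replicate 1 or 2 and 21 and 19 without RNAi replicate 1 or 2.

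The mRNA of ets-4 rose while no rise of its introns was detected. Its introns were at log2 -0.39 (SE 0.29, adjusted p = 0.923) in N2 and 0.17 (SE 0.29, adjusted p = 0.993) in glp-1. Its mRNA changed beyond its introns by 2.68 (SE 0.28, adjusted p = 0.000237) in N2 and 1.77 (SE 0.28, adjusted p = 0.0569) in glp-1. Under mock, intron counts per base over coding counts per base were 0.567 and 0.4585 for ets-4 in N2 and 0.4605 and 0.5072 in glp-1. The median gene was at 0.0156 and 0.0126 in N2 and 0.0172 and 0.0164 in glp-1. Whether all these intron counts came from unspliced ets-4 RNA was not tested, and its values beyond introns rest on them. Among 4999 genes in this test, rege-1 had the lowest p in N2, its introns having risen more than its mRNA (log2 -5.24, SE 0.35, adjusted p = 8.91e-07), and ets-4 had the next lowest. In glp-1 ets-4 had the lowest p (1.14e-05, edgeR). These were the 2 calls in N2, and edgeR, the one tool run for this test, made 0 calls in glp-1. An unadjusted p below 0.05 by edgeR was found for 218 genes in N2 and 251 in glp-1. Neither count exceeds by more than a trace the share that chance gives at that threshold. The next genes with a rise in N2, chosen after their values were seen, were ugt-37 (log2 2.48, adjusted p = 0.0816) and ugt-44 (log2 2.38, adjusted p = 0.161).

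A gene counted as a candidate target if its mRNA rose, and rose beyond its introns, in both strains. Among 130 genes with mRNA higher in both strains and testable introns, 0 met this rule at an adjusted p below 0.05 by edgeR. At an adjusted p below 0.1 the rule gave 1 gene, ets-4. It also gave ets-4 without N2 RNAi replicate 1 or without N2 RNAi replicate 2. In glp-1 the value of ets-4 passed (adjusted p = 0.0386) among genes with a mean of at least 20 intron counts. Low intron counts limit this test, and a gene that fell short of it is not shown to lack a change beyond its introns.

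The comparison of glp-1 with N2 under mock RNAi asks how the strains differed after mock feeding. The acyl-CoA dehydrogenase gene acdh-1 (WBGene00016943) was at 1389 ± 14.8 CPM in glp-1 against 8.221 ± 3.004 CPM in N2 (log2 7.40, SE 0.29, adjusted p = 3.17e-07). The other genes of the 5 largest rises were clec-134 (log2 3.98), Y37H2A.14 (3.64), K03B8.11 (3.55) and C16C8.19 (3.52). The 5 largest falls were those of F57F4.2 (log2 -4.38), the collagen genes col-161 (-3.19) and lon-3 (-2.97), the carnitine palmitoyltransferase gene cpt-4 (-3.17) and the transporter gene haf-6 (-3.03). F57F4.2 did not pass without N2 mock replicate 2 (adjusted p = 0.0589) or glp-1 mock replicate 1 (0.0574). In all, 995 genes were higher and 496 lower in glp-1 by edgeR. Their median coding lengths were 906 and 1500 bases, against 1095 for all tested genes. Across all tested genes the strain change fell with coding length (Spearman's rho -0.26), so part of these calls may follow length. With the trend of each library over coding length removed, 1025 genes were higher and 702 lower. With library size alone for scaling, 1478 were higher and 269 lower, and limma on the deposited log2 values gave 1521 and 268. The total of 1491 was 2447 with the mock libraries alone in the fit, 618 and 799 without N2 mock replicate 1 or 2, and 483 and 474 without glp-1 mock replicate 1 or 2. The labels do not give the temperature of N2, so strain and temperature cannot be separated here.

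Germline transcripts were present in the libraries labelled glp-1. Of 40 mitotic and meiotic germline genes, 5 were lower and 0 higher in glp-1 (5 and 0 adjusted over the list alone), with log2 changes from -1.09 to 0.09 and a median of -0.29, the helicase genes glh-1 (-1.09) and glh-2 (-1.08) being lowest (adjusted p = 2.16e-06, or adjusted p = 0.615 with an estimated correlation). The glp-1 gene itself was at 328 ± 7.36 CPM in glp-1 mock and 402 ± 90.5 CPM in N2 mock, and the germline gene gld-1 at 179 ± 2.14 and 228 ± 1.37 CPM. Of 52 other spermatogenesis genes, 14 were higher and 0 lower (26 and 0 adjusted over the list alone), including try-5 (1.85), with a median of 0.68 (adjusted p = 3.53e-08, or adjusted p = 0.615 with an estimated correlation). Of 32 oogenesis genes 0 passed (median -0.16, adjusted p = 0.0405, or adjusted p = 0.718 with an estimated correlation), and this call ended without N2 mock replicate 1 (adjusted p = 0.237) and glp-1 mock replicate 1 (0.068).

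C-type lectin genes were higher in glp-1 in 55 of 153 cases and lower in 7 (63 and 10 adjusted over the list alone), including clec-137 (log2 3.27). Neuropeptide and insulin genes were higher in 18 of 114 and lower in 1 (32 and 3 adjusted over the list alone), including ins-31 (3.34), and fatty acid synthesis genes were higher in 7 of 26 and lower in 0 (7 and 0 adjusted over the list alone), including the desaturase genes fat-5 (2.40) and fat-7 (1.87). Camera called these lists higher (adjusted p = 1.23e-20, 3.1e-06 and 0.0188), with adjusted p = 0.405, 0.644 and 0.615 with an estimated correlation. The fatty acid synthesis call ended without N2 mock replicate 2 (adjusted p = 0.115). Of 24 neuron markers 3 were higher and 0 lower (4 and 0 adjusted over the list alone, median 0.20), and that list was not called (adjusted p = 0.19).

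Cuticle collagen genes were lower in glp-1 in 45 of 130 cases and higher in 4 (54 and 6 adjusted over the list alone), including col-137 (log2 -3.53), and molting cycle genes lower in 10 of 70 and higher in 2 (11 and 3 adjusted over the list alone), including wrt-4 (-2.39). Lists with fewer changed members were mRNA decay factors (6 of 30 lower, 7 adjusted over the list alone), vitellogenins (4 of 6 and 4), heat shock proteins (3 of 14 and 5) and ribosomal proteins (1 of 77 and 0). These 6 lists were called lower (adjusted p = 5.9e-12, 0.0339, 7.17e-05, 0.00345, 0.0405 and 0.0292), with adjusted p = 0.615, 0.405, 0.405, 0.616, 0.718 and 0.932 with an estimated correlation. Without N2 mock replicate 2 the calls on vitellogenins (adjusted p = 0.181), heat shock proteins (0.432) and ribosomal proteins (0.181) ended, and without glp-1 mock replicate 1 those on heat shock proteins (0.141) and ribosomal proteins (0.0575). With the trend of each library over coding length removed, the calls on molting cycle genes (adjusted p = 0.188), vitellogenins (0.0916), heat shock proteins (0.0589) and oogenesis genes (0.0916) ended, which left 4 of 8 lists called lower. The other 22 lists tested were not called by camera, among them beta-oxidation genes, where acdh-1 and hphd-1 (log2 2.93) rose and cpt-4 fell. The median of that list was -0.12 and its mean 0.21, and camera ranked it higher (adjusted p = 0.3).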

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

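The tests on the reads of rege-1 and on germline transcripts were chosen after those results had been seen, and those on coding length before their results were seen. Several effects of the RNAi label differed between N2 and glp-1 by a test of the difference itself (N2 minus glp-1, log2, edgeR). In mRNA these were cyp-13A12 (3.55, SE 0.48, adjusted p = 0.0429), clec-72 (3.29, SE 0.37, adjusted p = 0.0162), clec-125 (2.49, SE 0.25, adjusted p = 0.00769) and cpt-3 (2.34, SE 0.29, adjusted p = 0.0248). All 4 calls ended without N2 mock replicate 1 (lowest adjusted p = 0.0656), N2 mock replicate 2 (0.0865) or glp-1 mock replicate 2 (0.0744). The call on cyp-13A12 also ended without N2 RNAi replicate 1 (0.0855) or 2 (0.163), glp-1 mock replicate 1 (0.166) or glp-1 RNAi replicate 1 (0.0987), that on clec-72 without glp-1 mock replicate 1 (0.0633) or glp-1 RNAi replicate 1 (0.061), and that on cpt-3 without N2 RNAi replicate 1 (0.0613), glp-1 mock replicate 1 (0.0707) or glp-1 RNAi replicate 1 (0.0799).

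The reads of rege-1 rose where its own RNAi was labelled, and the rise differed between the strains by 4.73 for introns (SE 0.52, adjusted p = 5.16e-05) and -4.16 for mRNA beyond introns (SE 0.48, adjusted p = 0.00168). Reads of fed double-stranded RNA from 1 construct do not account for the whole rise in both strains, by the intron counts added per coding count added. With each kind of count scaled to its library totals, these were 1.64 and 2.04 in the N2 libraries but 0.128 and 0.238 in those of glp-1, a ratio of 10.1. More transcription with unchanged processing is argued against as the whole rise in N2 by the mRNA change beyond introns of -5.24, whereas the value of -1.08 in glp-1 (SE 0.32, unadjusted p = 0.00449 by the edgeR quasi-likelihood F test, adjusted p = 0.706) missed the adjusted threshold set for excluding it there. An exchange of mock and RNAi labels was not excluded by the limit set for it, a percentile of 99. Among 4999 genes, the intron to coding density of rege-1 under the RNAi label lay at percentiles of 97.8 and 97.9 in N2. It lay at 78.0 and 81.1 in glp-1. In N2 the density was 0.683 and 0.667 under RNAi and 0.0165 and 0.0185 under mock, where the median gene was at 0.0156 and 0.0126. An exchange would put the high density in untreated N2 worms and the ordinary one in treated worms. These N2 values speak against an exchange without excluding it, and those of glp-1 do not decide. Fed RNA that differed between the strains, or double-stranded RNA next to changed transcription, may also contribute and was not tested.

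Germline transcripts were seen in the libraries labelled glp-1, for which the labels give 25 °C, taken here as the restrictive temperature. A germline absent from these animals is argued against, since 0 of 40 mitotic and meiotic genes were at least 4-fold lower than in N2 (log2 from -1.09 to 0.09) and, under mock, cbd-1 was at 1724 against 2213 CPM in N2 and oma-1 at 50.65 against 59.09 CPM. A smaller share of germline is argued against as the whole difference, since of 52 other spermatogenesis genes 14 were higher and 0 lower, with a median of 0.68 (camera adjusted p = 3.53e-08, or adjusted p = 0.615 with an estimated correlation). The separate list of major sperm proteins was not called in this comparison, so the point rests on the former list alone. An exchange of the strain labels cannot be told apart from the labels as given, because with a germline in both strains it would leave a small median of either sign, and that of the mitotic and meiotic genes was -0.29. Why germline transcripts were present was not tested, and strain and temperature cannot be separated, since the labels give no temperature for N2.

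Lists also differed between strains in the RNAi effect, by the median difference of antimicrobial peptides (-0.57, camera adjusted p = 1.27e-05), infection response genes (0.80, adjusted p = 3.12e-13), autophagy and lysosome genes (0.20, adjusted p = 0.00886) and neuropeptides and insulins (-0.22, adjusted p = 0.00604), all with adjusted p = 0.913 with an estimated correlation. The replicates of glp-1 RNAi differed with coding length (Spearman's rho across genes -0.44, with medians of 0.23 in genes up to 672 bases and -0.22 in genes from 1656 bases). The rho was -0.25 in N2 RNAi, 0.12 in N2 mock and -0.03 in glp-1 mock. The RNAi change itself followed coding length with a rho of 0.15 in N2 and -0.16 in glp-1. Across all tested genes the difference of the RNAi effect (N2 minus glp-1) also rose with coding length (Spearman's rho 0.25). With the length trend of each library removed, the difference of neuropeptides and insulins was -0.081 (adjusted p = 0.448), so a length trend may be its source. The trend is argued against as the whole cause for infection response genes (0.78, camera adjusted p = 7.89e-14) and autophagy genes (0.14, adjusted p = 0.0201). Antimicrobial peptides stayed called by camera (-0.42, adjusted p = 0.00853). Their median coding length of 226.5 bases lies at the short end, where the fitted trend may correct too little, so the test cannot decide for them. A response that depends on strain stays open for these lists, as does chance in view of the estimated correlation. Without glp-1 RNAi replicate 1 the antimicrobial call ended (adjusted p = 0.156) and neuropeptides and insulins turned (0.951), and the autophagy call ended without N2 mock replicate 1 (0.139) or N2 RNAi replicate 2 (0.243).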

How the results depend on the processing

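The removal of each library's length trend was chosen after the data had been seen, and the other alternatives were planned. Of 1580 values of named genes under other settings, 1520 kept their side of the threshold, and of 820 values with a library left out 681 did. In both sets 0 values changed direction where the main or the other fit passed the threshold. Changes of direction with neither fit past it were not counted. With a lone library in a group, it is assumed to vary like the others.

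Counts that moved by more than 1.5 times were these, and the cause was not tested. A replicate block gave 643 genes for RNAi in glp-1 and 48 for the difference (29 with the larger value in N2 and 19 in glp-1), although deviations of like-numbered replicates correlated across genes by 0.169 in N2 and -0.037 in glp-1. For the difference, no filter gave 11 genes, DESeq2 30 and the length trend removed 12. For strain, the mock libraries alone gave 2447. For introns in N2, library size alone gave 28, the compared groups alone 28 and DESeq2 31, and in glp-1 no filter gave 59, the compared groups alone 53 and DESeq2 21. For mRNA beyond introns, no library block gave 4 genes in N2, and a mean of at least 20 intron counts, which tests fewer genes, gave 1 in glp-1. Candidate targets numbered 1 at an adjusted p below 0.1 and 89 when no intron call replaced the test beyond introns. With an estimated correlation 0 lists were called in every contrast (lowest adjusted p 0.0875 in N2, 0.0726 in glp-1, 0.913 for the difference and 0.405 for strain), and fry, which does not compare a list with other genes, called 5 lists in glp-1, 0 for the difference and 5 for strain. Of those 5 for strain, 4 were also called by camera in the same direction. In N2 fry called 10 lists, of which 9 were. Under the replicate block, lists called lower in glp-1 against N2 went from 8 to 3: heat shock proteins turned higher (adjusted p = 0.601), and the calls on vitellogenins (0.0659), oogenesis genes (0.0659), molting cycle genes (0.0902) and ribosomal proteins (0.446) ended. With the length trend removed, calls ended in N2 for ETS factors (0.0634) and glutathione S-transferases (0.0658) and in glp-1 for neuropeptides and insulins (0.0985).

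With each library of the groups compared left out in turn, the counts ranged from 423 to 682 for RNAi in N2, 188 to 1491 in glp-1, 0 to 405 for the difference, 474 to 799 for strain, 28 to 42 for introns in N2, 8 to 21 for introns in glp-1 and 0 to 1 for candidate targets. For mRNA beyond introns they were 2 in N2 without any 1 of the 4 N2 libraries and 0 in glp-1 without any 1 of the 4 glp-1 libraries, while without either N2 RNAi library ets-4 passed in glp-1. Lists called ranged from 13 to 17 in N2, were 13 in glp-1, and ranged from 4 to 10 for the difference and 9 to 13 for strain. Without glp-1 RNAi replicate 1, lists turned in glp-1 for antimicrobial peptides (lower, adjusted p = 0.0474), neuropeptides and insulins (lower, 0.851) and ribosomal proteins (lower, 0.00591), and in the difference for neuropeptides and insulins (0.951) and ribosomal proteins (0.0109). With other single libraries left out, these adjusted p ranged in glp-1 up to 0.762 for antimicrobial peptides, which were also lower without glp-1 mock replicate 1 (0.556), from 2.5e-05 for neuropeptides and insulins and from 1.25e-05 to 0.454 for ribosomal proteins, and in the difference from 2.5e-06 for neuropeptides and insulins and from 2.88e-07 to 0.761 for ribosomal proteins. Library size alone moved the median of all genes by 0.13 for strain, with 84.6% of the called genes higher against 66.7% with TMM, and for introns to -0.14 in N2 and 0.15 in glp-1.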

Other observations

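The tests of the propionate shunt and of the methionine cycle were set before their results were seen, on genes chosen because acdh-1 had stood out. The propionate shunt genes acdh-1 and hphd-1 were higher in glp-1 than in N2. The gene acdh-1 was at 8.221 ± 3.004 CPM in N2 mock, 3.87 ± 1.01 CPM in N2 RNAi, 1389 ± 14.8 CPM in glp-1 mock and 1130 ± 47.8 CPM in glp-1 RNAi (n = 2 libraries each). The dehydrogenase gene hphd-1 was at 31.8 ± 2.17, 33.8 ± 3.80, 242 ± 10.4 and 222 ± 6.06 CPM in these groups.

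A hypothesis is that the shunt as a whole is induced in the animals labelled glp-1, as low vitamin B12 is known to do. Its other 3 enzymes were at log2 1.5 (ech-6, SE 0.15, adjusted p = 9.49e-05), 0.78 (hach-1, SE 0.15, adjusted p = 0.00915) and 0.49 (alh-8, SE 0.16, adjusted p = 0.0725). Their median of 0.78 lay at percentile 99.99 of 10000 random lists matched on expression. Such lists may lie mostly below 0, as those for the methionine cycle did, so the percentile may overstate the rise. The rises of ech-6 and hach-1 themselves go with induction of the shunt, while that of alh-8 missed the threshold. The 7 genes of the methionine cycle had a median of -0.01, with log2 changes from -0.13 (cbs-1) to 0.28 (pmt-2, edgeR adjusted p = 0.289, the lowest of the 7). That median lay at percentile 95.19, since most matched random lists lay below it, and not because these genes rose. It fell short of the limit set for it. With SE from 0.12 to 0.16, the changes argue against a 2-fold rise of these 7 mRNAs. A smaller effect reaching that cycle cannot be told apart from none. Strain, temperature and food may each be a source, and none could be separated by these libraries.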
